A study of Mus musculus with 6 samples.

How the data were processed

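ChIP-seq of H3K79me2 (Abcam ab3594) and H3K79me3 (Diagenode) was done on hematopoietic progenitors from mouse bone marrow transduced with MLL-AF9 WT, D544R or D546R. There was 1 library for each of the 3 genotypes and 2 marks. Per the labels, cross-linked chromatin was sonicated to about 300 bp, libraries were made with a TruSeq ChIP kit and the reads of several runs were merged. Per the submitters' processing notes, Bowtie, bedtools, DESeq and the mm9 build were used, and their roles and versions are not given in the sources used here. The deposited table holds raw read counts per gene, per the file headers over a region from 2 kb before the transcription start to the transcript end, with no normalization. Whether duplicate reads were removed is not given in the sources used here. Column values were whole numbers with a different total in each library.

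The table had 24012 genes, each symbol once, with a RefSeq identifier and coordinates but no strand. The side of the 2 kb extension of minus-strand genes was therefore not checked, and exons and GC content could not be assigned. The median region was 15.9 kb long. Of all regions 9875 (41.1%) overlapped another and 193 shared both ends with another, so their counts are not independent. Only counts over genes were available. A change of the mark across the whole genome cannot be seen after scaling, and input or spike-in reads were not used here.

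Size factors were computed as the median of ratios over the 3 libraries of each mark, from the 23029 genes (H3K79me2) and 20863 genes (H3K79me3) with a count in all 3. They were 1.35, 0.972 and 0.764 for WT, D544R and D546R in H3K79me2 and 0.982, 0.872 and 1.17 in H3K79me3. The log2 ratio of normalised counts used a prior count of 0.5. Its 95% counting interval was the exact conditional binomial (Clopper-Pearson) interval. A gene was past the 2-fold rule when its ratio was at least 2-fold, its counting interval excluded no change and its mean normalised count over the 3 libraries was at least 100. The rule is not a significance test, since 1 library per group gives no error between cultures. Comparisons were D544R against WT, D546R against WT and D546R against D544R in each mark. Totals of 3558329 to 6652571 counts per library gave the counting precision printed with each gene.

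Reads per independent fragment were estimated for each library from the share of the 4591 autosomal regions shorter than 5 kb that had no count, which treats every such region as reachable. Unreachable regions or an uneven signal would also leave regions at 0, so the estimate is an upper one in H3K79me2 above all. Intervals printed beside genes divide counts by this number and are called fragment intervals here.

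Before the data were examined, 18 gene lists with 367 genes, the comparisons, the thresholds, the first set of alternatives and the rule for named genes were fixed. The lists were the HoxA cluster, HoxA flanking genes, the HoxB, HoxC and HoxD clusters, MLL fusion targets outside HoxA, and DOT1L and elongation complex genes. Lists of blood cells were stem and progenitor, granulocyte and monocyte progenitor, mature myeloid, erythroid and megakaryocyte, lymphoid, and mast cell and basophil genes. The others were MYC and ribosome assembly, ribosomal protein, housekeeping, cell cycle, interferon response, cell cycle inhibitor and p53 genes, and silent genes of other tissues. Of the listed genes, 1 (Ly6g) was not in the table. For each list the median log2 ratio of members with a mean of at least 10 was ranked among 10000 random lists of the same size matched on mean count in 20 bins. A percentile below 2.5 or above 97.5 lay outside the middle 95%. Random lists drew genes from anywhere, so percentiles of lists of neighbouring genes such as HoxA, which do not vary independently, are too extreme.

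Named genes were, per mark and mutant against WT, the 8 lowest and 8 highest past the rule without predicted models, Mir, Snor and histone names. To these came fixed genes (among them Hoxa5, Hoxa7, Hoxa9, Hoxa10, Meis1, Pbx3, Mef2c, Cdk6, Eya1, Jmjd1c, Runx1, Flt3, Myb, Actb and Gapdh) and the lowest and highest member of each list. Together they were 166 genes. Genes named outside this rule, among them members of the lists and genes past the rule in both marks, were chosen after their values were seen.

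The difference between marks was the log2 ratio in H3K79me3 minus that in H3K79me2. Correlations across genes were set beside 20 simulated sets of unchanged libraries sharing the WT library, drawn as single reads or as clumps. The concentration of counts was the share of a library in the 10% of genes with the most counts in the WT library of the other mark.

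Alternatives were total counts, edgeR TMM factors, size factors over all 6 libraries, the silent gene list as the reference, a mean of at least 300 or no filter, a 1.5-fold threshold, other matching of random lists, summed counts, members of a mean of at least 100, and other shares of genes for the concentration. Those added after the values were seen were fragment intervals, a mean of at least 1000, leaving out overlapping regions, and ranking or matching on counts per kb in the library outside the ratio.

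The procedure was tested on simulated data with 24012 genes. With single reads 0% of unchanged genes were past the rule, and with clumps of duplicates 0.40% in H3K79me2 and 6.08% in H3K79me3 for D546R against WT. In H3K79me3 this became 2.11% with fragment intervals in the rule. With clumps, a 3-fold lower signal was recovered in 77.4% of 31 genes in H3K79me2 and in 62.5% of 24 genes in H3K79me3, the last becoming 50.0% with fragment intervals. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors alone.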

Results

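Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured 2 marks of histone H3, di- and trimethylation of lysine 79 (H3K79me2 and H3K79me3), in mouse bone marrow progenitors. The cells carried a retrovirus expressing the leukemia fusion protein MLL-AF9 as WT, D544R or D546R. DOT1L is the enzyme that methylates H3K79, and AF9 is one of its binding partners. Each of the 3 genotypes gave 1 library per mark, so there were 6 groups of 1 library and no replicates. No test between groups was possible, and every interval given here covers counting error only, not variation between cultures. The values were read counts for 24012 genes over a region that started 2 kb before the transcription start and ended at the transcript end.

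In H3K79me2 the libraries held 5993741 counts (WT), 4287873 (D544R) and 3558329 (D546R). In H3K79me3 they held 5859821 (WT), 5207395 (D544R) and 6652571 (D546R). The gene with the most counts was Arid1b in WT, Baz2b in D544R and Chl1 in D546R in H3K79me2, and Cntnap2, Ptprd and Cntnap2 in H3K79me3. A count of 0 in a library allowed up to 3 counts. Regions with no count numbered 138, 164 and 795 in the H3K79me2 libraries and 1063, 983 and 2203 in the H3K79me3 libraries, each in the order WT, D544R, D546R. The share of regions shorter than 5 kb with no count implied 4.10, 3.30 and 4.84 reads per independent fragment in H3K79me2 and 9.80, 8.17 and 18.8 in H3K79me3. The printed gene intervals were widened by these factors unless they are called counting intervals, which do not allow for duplicate reads and are narrower.

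D546R against WT in H3K79me2 addressed whether dimethylation of genes bound by the fusion depends on the exchanged residue. The genes with the lowest ratios were led by targets of MLL fusions that keep progenitors self-renewing. The homeobox gene Hoxa7 (NM_010455, mm9 chromosome 6, 52163622 to 52168572) had 254 counts in WT and 2 in D546R, a log2 ratio of -5.85 (counting interval -9.22 to -4.30). Its fragment interval was -18.2 to -2.67. Hoxa10 (NM_001122950, chromosome 6, 52179195 to 52190853) stood at -2.77 (-4.39 to -1.55) and Hoxa9 (NM_001277238, chromosome 6, 52171095 to 52177369) at -2.49 (-3.84 to -1.41). Meis1 (NM_010789, chromosome 11, 18778430 to 18918972), the partner of HOXA9 in leukemia, had 7372 counts in WT and 480 in D546R and was 8.70-fold lower, with a log2 ratio of -3.12 (-3.43 to -2.83). The region of Hoxa7 overlapped 1 other region and that of Hoxa10 overlapped 2, so they share counts with neighbours.

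The developmental regulator Eya1 (NM_001252192, chromosome 1, 14157038 to 14300280) had a log2 ratio of -1.69 (-2.14 to -1.26). The transcription factors Mef2c and Runx2 stood at -1.43 (-1.72 to -1.16) and -1.62 (-1.81 to -1.43). The histone demethylase family gene Jmjd1c was at -1.02 (-1.18 to -0.87) and the remodeler gene Chd9 (NM_177224, chromosome 8, 93350733 to 93578407) at -2.02 (-2.27 to -1.77). Cenpv, which encodes a centromere protein, was at -2.40 and Bahcc1, a chromatin reader gene, at -2.06. Not every target was past the 2-fold rule: the cell cycle kinase gene Cdk6 stood at -0.93, Pbx3 at -0.44, Flt3 at -0.35 and Myb at -0.13. In WT the counts per kb over the whole region were 1.04 and 1.70 times those of the silent genes for Flt3 and Pbx3. They were 12.9 and 6.82 times for Cdk6 and Myb. An average over a long region can dilute a signal in part of it. How much signal Flt3 and Pbx3 had to lose is therefore not settled. Hoxa5, with 43 and 2 counts, was below the count minimum of 100, and its log2 ratio was -3.30 (counting interval -6.70 to -1.67). Runx1 was higher by 0.68 (0.53 to 0.83), short of 2-fold. The reference genes Gapdh and Actb were at 0.02 and 0.85, with fragment intervals that included no change. The counting interval of Actb, 0.40 to 1.31, excluded it.

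Genes at least 2-fold higher in D546R in H3K79me2 included genes of mature myeloid cells. Chil3 (NM_009892, chromosome 3, 105948471 to 105970482), a chitinase-like protein of neutrophils and macrophages, had 157 counts in WT and 348 in D546R, 3.90-fold higher with a log2 ratio of 1.96 (1.38 to 2.57). The survival gene Bcl2a1b was at 1.57, the adhesion gene Ceacam1 at 1.54, Ankrd22 at 1.45 and the chemokine receptor gene Ccr1 at 1.38. Klf5, Pnoc and Tespa1 each stood at 1.42. Of 8905 genes with a mean normalised count of at least 100, 77 were at least 2-fold lower and 79 at least 2-fold higher. This balance depended on the scaling between libraries: it was 100 lower and 59 higher with total counts, 72 and 106 with size factors over all 6 libraries, and 144 and 30 with the list of silent genes as the reference. At a mean of at least 1000 the counts were 20 lower and 1 higher among 899 genes. Under the rule at a mean of at least 100, unchanged libraries simulated as clumps of duplicates gave 26.15 lower and 14.55 higher.

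**Figure D1:**
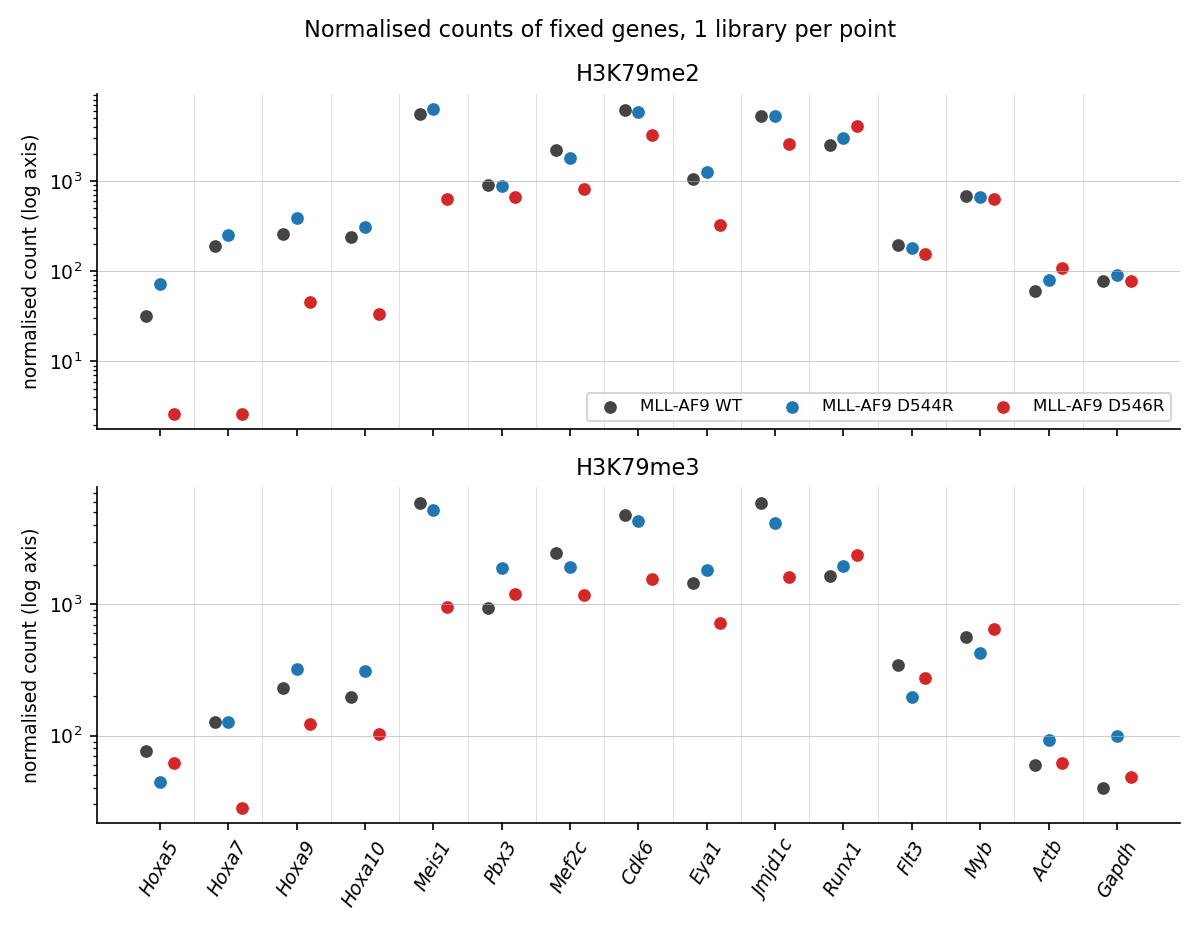
Normalised count (vertical log axis) of genes fixed in advance, with H3K79me2 above, H3K79me3 below and 1 point per library. The log2 ratio of Meis1 to WT was -3.12 in D546R and 0.21 in D544R in H3K79me2.

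D544R against WT in H3K79me2 addressed the same question for the other exchanged residue. Meis1 and the HoxA genes past the rule in D546R were not lower in D544R. Meis1 had 6154 counts in D544R, a log2 ratio of 0.21 (0.11 to 0.30), and Hoxa9, Hoxa7 and Hoxa10 stood at 0.58, 0.42 and 0.39. Jmjd1c was at 0.02, Cdk6 at -0.09 and Mef2c at -0.29, none of them past the 2-fold rule. The gene that was lower was Chl1 (NM_007697, chromosome 6, 103458869 to 103683029), which encodes a neural cell adhesion molecule: 5922 counts in WT and 1653 in D544R gave -1.37 (-1.52 to -1.22). Its ratio in H3K79me3 was -0.41 (-0.58 to -0.24). Of the 8905 genes it was the 1 gene lower, and 3 were higher: Odf2, a centriole and sperm tail gene, at 1.12, the lineage regulator gene Zbtb7b at 1.07, and the small RNA gene Snord95, named after its values were seen. The standard deviation of the log2 ratios across genes was 0.21 here and 0.40 for D546R.

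D546R against WT in H3K79me3 addressed whether trimethylation depends on the same residue. Among genes with many counts, several of the fusion targets were again lower, while Runx1 (0.55), Pbx3 (0.34) and Myb (0.20) were not past the rule. In WT their counts per kb in this mark were 2.11, 1.36 and 4.37 times those of the silent genes. Meis1 had 5842 counts in WT and 1118 in D546R, a log2 ratio of -2.64 (-3.05 to -2.25). Runx2 was at -1.97, Jmjd1c at -1.87, the repressor gene Zeb2 at -1.84, Cdk6 at -1.60, the splicing regulator gene Mbnl1 at -1.46, Mef2c at -1.07 and Eya1 at -1.01. Chd9 was at -1.72 (-2.11 to -1.36) and Skap2, an adaptor gene beside the HoxA cluster, at -1.67 (-2.05 to -1.31). Tsc22d2 (chromosome 3), a gene of the leucine zipper family named after its values were seen, had 6649 counts in WT and 728 in D546R, -3.44 in H3K79me3 and -1.95 in H3K79me2.

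The HoxA genes were less clear in this mark. Hoxa3 was the 1 member past the 2-fold rule, at -1.46 (-2.59 to -0.47). Hoxa7, Hoxa10 and Hoxa9 stood at -2.16, -0.95 and -0.92 with intervals that included no change. Of the 11 members 9 were below 0, the lowest being Hoxa13 at -7.60, which was not past the rule. Hoxa11 and Hoxa2 had few counts in WT and went the other way. Hoxa11, with 2 and 108 counts, was at 5.19 (counting interval 3.62 to 8.57), and Hoxa2, with 6 and 23, at 1.60 (counting interval 0.35 to 3.27). Against the same WT library Hoxa11 was also at 4.33 in D544R. The lowest ratios belonged to genes with few counts in D546R. Nhlrc3, with 107 and 1 counts, was at -6.41 (counting interval -12.31 to -4.48), and the noncoding RNA gene Fendrr, with 169 and 3, at -5.85 (counting interval -8.36 to -4.50). Ms4a7, a macrophage membrane gene, stood at -4.73, Zeb2os, antisense to Zeb2, at -4.66, Parp12 at -4.64, the DNA polymerase gene Pold1 at -4.40 and Ttc5 at -4.08. Fmr1, which encodes the fragile X protein, had 716 counts in WT and 65 in D546R, -3.70 (-5.81 to -2.20).

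Of the genes higher in D546R in H3K79me3, the myeloid genes Chil3 (1.84), Ccr1 (2.12) and Ankrd22 (1.40) were also higher in H3K79me2. The 8 highest had at most 29 counts in WT: the hair keratin gene Krt25 (3.73), the homeobox gene Hlx (3.63), Ankrd34b (3.19), Pdlim2 (3.12), Fam199x (3.11), Zfp202 (3.11), Cyb561a3 (3.01) and Afg3l1 (3.01). Of 10824 genes, 965 were at least 2-fold lower and 751 at least 2-fold higher. With the list of silent genes as the reference these were 2906 and 180. With intervals from estimated fragments they were 597 and 459. Unchanged libraries simulated as clumps of duplicates gave 351 and 273 under the same rule without fragment intervals. At a mean of at least 1000, 72 of 1247 genes were lower and 0 higher. Loss followed signal density: the densest 10% of these genes by counts per kb, 125 genes, had a median of -0.83, against -0.04 for the others, and held 47 of the 72.

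**Figure D2:**
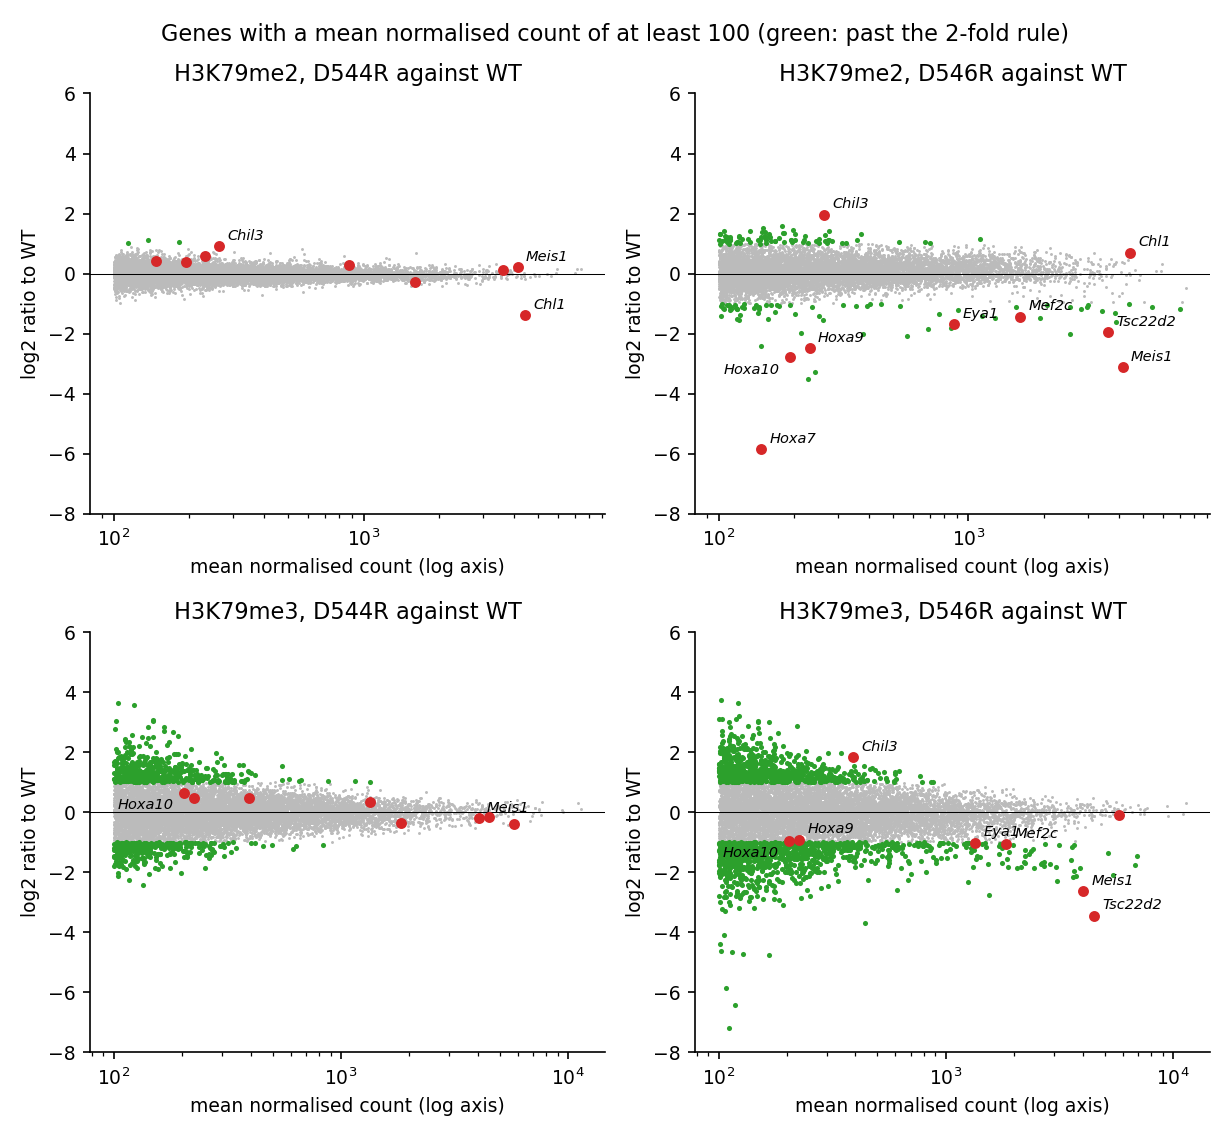
Log2 ratio to WT (vertical axis) against mean normalised count (log axis) for each mark and mutant. Green points passed the 2-fold rule; red points are Hoxa7, Hoxa9, Hoxa10, Meis1, Eya1, Mef2c, Tsc22d2, Chil3 and Chl1, and in H3K79me3 the spread was wider at low counts.

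D544R against WT in H3K79me3 addressed trimethylation for the other residue. Meis1 stood at -0.20 (-0.37 to -0.03), Hoxa9 at 0.48 and Hoxa10 at 0.65, none past the 2-fold rule. Jmjd1c was at -0.51 (-0.69 to -0.33). Pbx3, a cofactor gene of the HOX proteins, had 922 counts in WT and 1642 in D544R, a log2 ratio of 1.00 (0.64 to 1.37). Among the lowest were the zinc finger gene Zfp616 (-2.41), Tspan4 (-2.25), the cytoskeletal linker gene Plec (-2.06), Dnal1 (-2.02), the eye regulator gene Pax6 (-2.02), Surf6 (-1.89) and Ccdc37 (-1.89). The highest were D7Ertd715e (3.63), Ankrd34b (3.57), Rgma (3.08), Afg3l1 (3.04), Krt25 (3.04), Ankmy1 (2.85), Gprasp1 (2.84) and Zfand2a (2.79), each with at most 30 counts in WT. Of 10824 genes 327 were lower and 472 higher, 178 and 313 with intervals from estimated fragments, and 1998 and 97 with the silent genes as the reference. Simulated clumps without change gave 172 lower and 172 higher under the rule. At a mean of at least 1000 there were 0 lower and 2 higher.

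D546R against D544R addressed whether the mutants differ from each other. Hoxa9, Hoxa10 and Meis1 were lower in D546R in both marks. In H3K79me2 Hoxa7 was at -6.27, Meis1 at -3.33 (-3.64 to -3.04), Hoxa10 at -3.16, Hoxa9 at -3.07 and Eya1 at -1.97. In H3K79me3 Meis1 was at -2.44 (-2.85 to -2.05), Hoxa10 at -1.60 and Hoxa9 at -1.40. Chl1 was higher in D546R in H3K79me2 by 2.07 (1.92 to 2.23). Spi1, which encodes the myeloid regulator PU.1, was higher in H3K79me3 by 1.58 (0.80 to 2.40), and Plec by 3.17. In H3K79me2, 78 genes were lower and 69 higher. These were 109 and 38 with total counts, 62 and 87 with size factors over all 6 libraries, and 132 and 29 with the silent genes as the reference. In H3K79me3, 899 were lower and 625 higher, against 774 and 749 with total counts, 554 and 403 with intervals from estimated fragments, and 39 and 0 at a mean of at least 1000.

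As a group, the HoxA cluster, whose genes keep progenitors immature, had a median log2 ratio of -2.16 in D546R in H3K79me2, below all of 10000 random lists with matched counts (percentile 0), with all 4 members of a mean of at least 100 lower. In D544R its median was 0.40 (percentile 99.7), with no member past the rule. The HoxA genes are neighbours and some of their regions overlap, while the random lists drew genes from anywhere. The HoxA percentiles in both marks therefore overstate how unusual the list is. In H3K79me3 the medians were -1.46 (percentile 0.14) in D546R and 0.21 (75.1) in D544R, the second turning to -0.35 with the silent genes as the reference. Over the 3 members of a mean of at least 100 the first was -0.95 and inside the middle 95% (3.27). The 25 other fusion targets, which include Meis1, Mef2c and Runx2, had medians of -0.46 in H3K79me2 and -0.68 in H3K79me3 in D546R, both at percentile 0. Of these targets 8 were lower in H3K79me2 and 10 in H3K79me3, or 8 and 9 with fragment intervals, which Gfi1 did not pass in H3K79me3. Against random lists of equal counts per kb the percentile in H3K79me3 was 3.47, or 0.47 over the 21 members of a mean of at least 100. In D544R their medians were -0.01 (66.3) and -0.15 (4.60).

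Genes of mature myeloid cells, such as the granule gene Ltf and Chil3, had a median of 0.79 in D546R in H3K79me2 (percentile 100) and 0.18 in D544R (95.4). Of the 22 members measured, 5 had a mean of at least 100, and 2 were past the rule in D546R and 0 in D544R. The D544R median lay outside the middle 95% with those 5 members alone (99.6), without matching (98.7) and with lists of equal counts per kb (99.1). In H3K79me3 both medians were 0.34 (85.0 and 92.5), and with the silent genes as the reference they were -0.22 and -0.23. Cell cycle genes stood at 0.27 in D546R in H3K79me2 (98.6; 82.4 with lists of equal counts per kb) and 0.07 in H3K79me3 (61.3). Silent genes of other tissues had medians of 0.00 in H3K79me2 (71.7) and 0.89 in H3K79me3 (99.7) in D546R, and in D544R 0.81 in H3K79me3 (99.98). Housekeeping genes were at 0.16 and 0.04 in D546R, and at -0.33 in D544R in H3K79me3 (2.27; 14.8 with lists of equal counts per kb).

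The remaining 12 lists lay within the middle 95% of matched lists in both marks and both mutants. With lists of equal counts per kb 3 of them left it: MYC and ribosome assembly genes in D546R in H3K79me2 (1.65), ribosomal protein genes in D546R in H3K79me3 (97.6), and granulocyte and monocyte progenitor genes in D544R in H3K79me2 (97.7). Among all lists but HoxA, the other fusion targets and mature myeloid genes, matching on count and length moved 2 percentiles out of the middle 95% and 2 into it. Members of a mean of at least 100 moved 3 out and 2 in. In D546R, H3K79me2 first and H3K79me3 second, the medians were -0.06 and -0.08 for the genes flanking HoxA and -0.34 and 0.42 for the HoxB, HoxC and HoxD clusters. They were 0.15 and -0.06 for genes of the DOT1L and elongation complexes, and -0.08 and 0.11 for stem and progenitor genes. Granulocyte and monocyte progenitor genes had 0.19 and 0.08, erythroid and megakaryocyte genes -0.02 and 0.33, lymphoid genes -0.13 and 0.07, and mast cell and basophil genes 0.32 and 0.00. Genes of MYC and ribosome assembly had -0.06 and -0.34, ribosomal protein genes 0.01 and 0.09, interferon response genes 0.11 and 0.06, and cell cycle inhibitor and p53 genes 0.06 and 0.24. In D544R the lists inside the middle 95% had medians from -0.12 to 0.18 in H3K79me2 and from -0.32 to 0.34 in H3K79me3. Setting members at 0 counts to the floor of 3 counts turned 1 of these, erythroid and megakaryocyte genes in D544R in H3K79me3, from -0.08 to 0.06, and moved lymphoid genes there from 0.07 to 0.12. Taking the silent genes as the reference moved the median of all genes by -0.56 in each mutant in H3K79me3 and by -0.16 in D546R in H3K79me2, so smaller positive medians change sign.

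**Figure D3:**
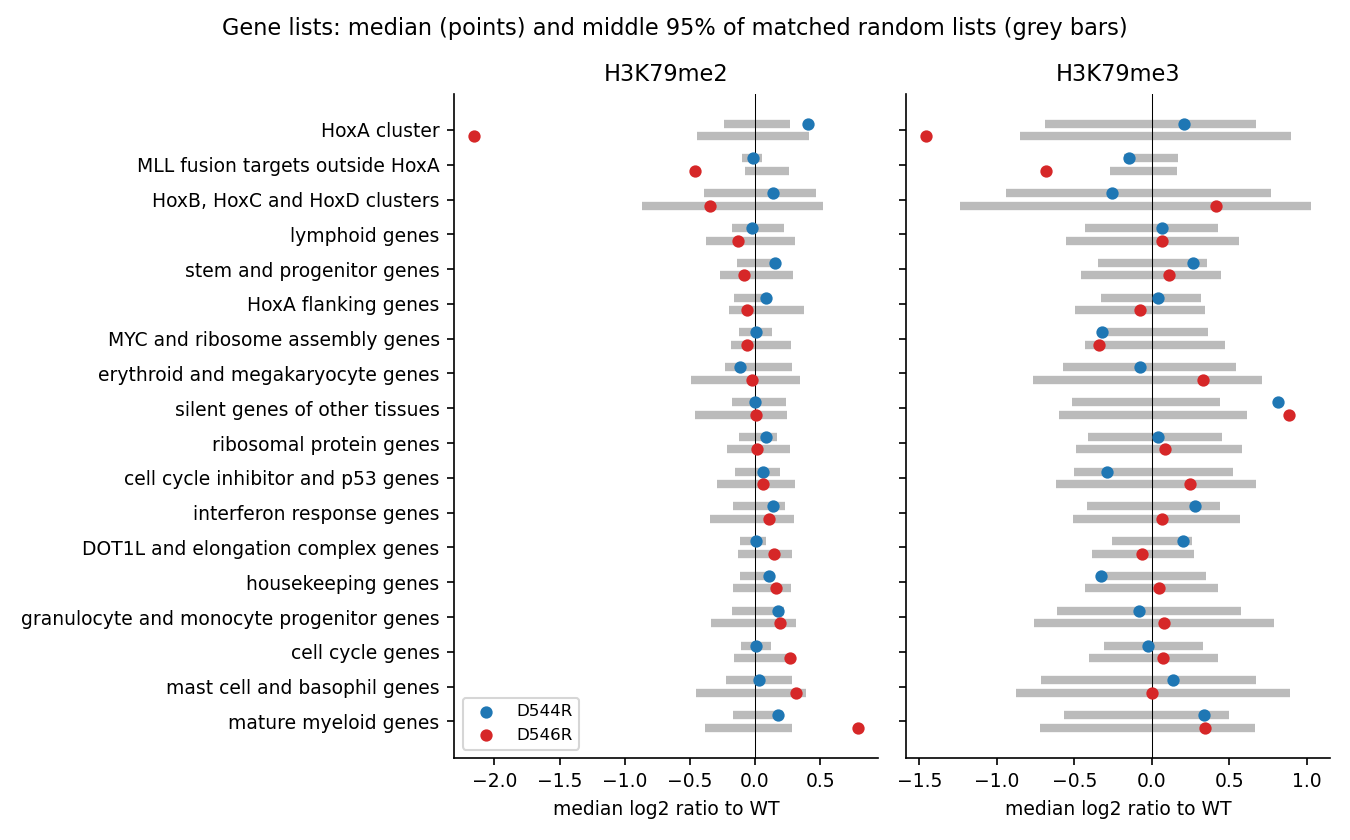
Median log2 ratio to WT of the 18 fixed gene lists in each mark and mutant, with the middle 95% of random lists of matched counts. The HoxA cluster stood at -2.16 in H3K79me2 in D546R, outside that range.

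The comparison of the marks addressed whether di- and trimethylation differ in the same genes. Across genes, which are not independent replicates, the log2 ratios of D546R in the marks correlated with r of 0.13 at a mean of at least 100 and 0.58 at a mean of at least 1000. At a mean of at least 300 in both, 26 genes were at least 2-fold lower in both marks, against 1.74 from the sizes of the sets. At a mean of at least 100, 35 were lower in both, 13 higher in both and 7 in opposite directions. In D544R r was 0.04, and no gene was past the rule in both. In D546R the difference between marks over the HoxA cluster had a median of 1.70 (percentile 99.9), less lowered in H3K79me3. Medians of the same 10 members were -2.16 in H3K79me2 and -1.20 in H3K79me3. Redrawing counts as estimated fragments gave the list medians standard deviations of 0.62 in H3K79me2 and 0.49 in H3K79me3, the second over 11 members. The size of this gap is therefore uncertain. Mature myeloid genes differed by -0.74 (2.45) in D546R, a percentile that became 6.88 with length matched. In D544R, MYC and ribosome assembly genes differed by -0.43 (0.80), genes of the DOT1L and elongation complexes by 0.26 (97.6) and silent genes by 0.94 (99.97). With the silent genes as the reference these were -0.95, -0.26 and 0.37, so the sign of the DOT1L and elongation complex value depends on the scaling.

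The mutants were compared with each other through the same WT library, which alone makes their ratios correlate. In H3K79me2 r across genes was 0.29, against 0.39 in unchanged libraries simulated as single reads and 0.40 in those simulated as clumps of duplicates. In H3K79me3 it was 0.42, against 0.50 for single reads and 0.44 for clumps. At a mean of at least 300 it was 0.47, against 0.50 and 0.44. In H3K79me3 85 genes were lower in both mutants and 212 higher in both, where single reads gave 0 and 0 and clumps 25.4 and 76.2.

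Concentration of counts was compared through the 10% of genes with the most counts in the WT library of the other mark. Counts were not divided by length here, so these genes may be long rather than densely methylated. In H3K79me2 these genes held 55.1% of WT counts, 54.2% of D544R counts and 54.0% of D546R counts. In H3K79me3 they held 54.8%, 53.6% and 51.8%. The exact Clopper-Pearson 95% interval of the last was 51.78 to 51.86%. It takes each read as independent, so it is too narrow if the estimated 18.8 reads per fragment of this library holds. Ranked by counts per kb, the difference from WT was -3.33 percentage points in D544R and -5.18 in D546R in H3K79me3, and 0.23 and -0.18 in H3K79me2.

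**Figure D4:**
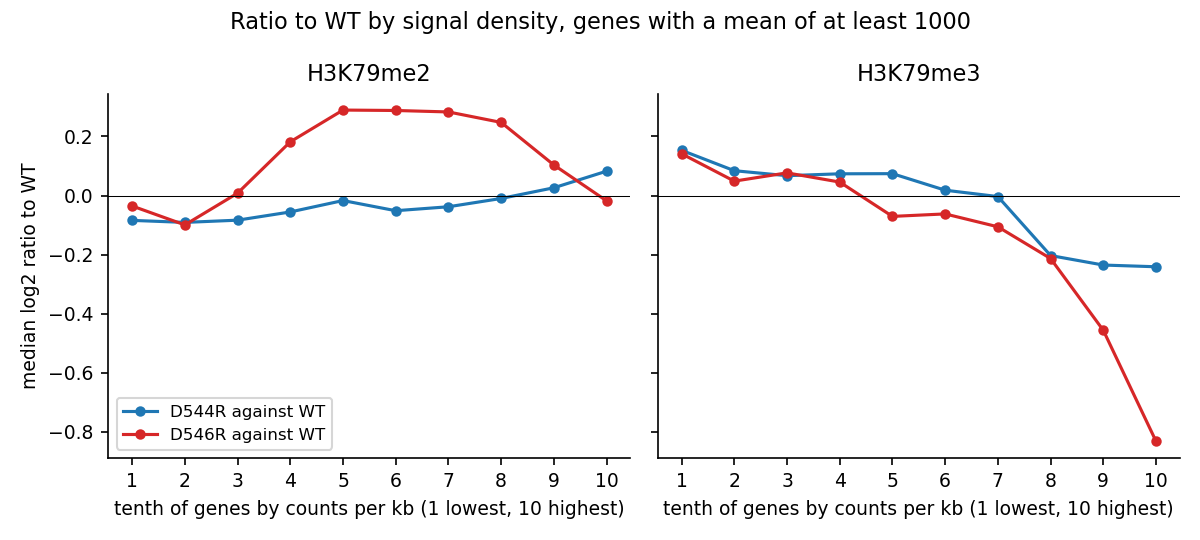
Median log2 ratio to WT (vertical axis) in 10 bins of signal density (horizontal axis, counts per kb), for genes with a mean normalised count of at least 1000. In H3K79me3 the densest bin stood at -0.83 in D546R and -0.24 in D544R, and in H3K79me2 at -0.02 and 0.08.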

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

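All tests of explanations in this part were chosen after the result was seen. Of the named genes, 6 were past the 2-fold rule in at least 1 mutant and had fragment intervals on opposite sides of no change in D544R and D546R. So did 1 gene list, by its percentiles. The difference was not tested since each group had 1 library, and genes outside the naming rule, such as Hoxa3 (0.46 and -2.01) and Tsc22d2 (0.13 and -1.95) in H3K79me2, did so too. In H3K79me2, with D544R first, these were Meis1 (0.21 and -3.12), Hoxa9 (0.58 and -2.49), the HoxA cluster as a list (0.40 and -2.16), Eya1 (0.28 and -1.69), the chromatin reader gene Bahcc1 (0.82 and -2.06) and the neural adhesion gene Chl1 (-1.37 and 0.70). In H3K79me3 they were Eya1 (0.33 and -1.01) and Nhlrc3 (1.16 and -6.41, from 1 count in D546R).

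The HoxA cluster and the other MLL fusion targets had medians below matched lists in D546R in both marks, Meis1 and Runx2 being past the rule in both and Runx1 in neither. A weaker pull-down, which lowers dense genes most, was argued against in H3K79me2: the median of the other targets was -0.46, outside the range of lists of equal counts per kb (-0.10 to 0.32), and that of HoxA lay lower. In H3K79me3 it stays open, since members with few counts decide: HoxA stood at -1.46 (percentile 0.65), with 14.5 over its 3 members of a mean of at least 100, and the other targets at -0.68 (3.47), with 0.47 over 21 such members, where below 2.5 was required of both. Chance clumps of duplicates were argued against, for genes of a mean of at least 300 in both marks, by 26 genes lower in both. There 1000 random pairings gave 5 at the upper end. Hoxa7, Hoxa9 and Hoxa10 had lower means in H3K79me2 and were outside this test. Their fragment intervals lay below 0 in H3K79me2 and included no change in H3K79me3, where clumps stay open for them. Fewer progenitors, as the cause at HoxA, were argued against by stem and progenitor genes that stood 2.05 above HoxA with a standard deviation of 0.61. For the other targets that gap was 0.35, which together with the higher mature myeloid genes (0.79 in H3K79me2) leaves a shift to mature cells open beside the effect of the genotype and a difference of the 1 D546R culture from the others.

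H3K79me3 had many more genes past the 2-fold rule than H3K79me2. For genes such as Krt25 and Hlx, higher in D546R, few fragments with many duplicates are a candidate explanation of part: 0% were past the rule at a mean of at least 1000, against 11.3% at 100 to 300, although simulated clumps gave 273 higher genes and 751 were seen. Duplicates were argued against for the lower genes of a mean of at least 1000, such as Tsc22d2 and Meis1, since 72 were lower and 0 higher there, where clumps act both ways; they stay open for the 716 lower genes at 100 to 300, with 351 lower genes of any depth in simulated clumps and 965 seen. A scaling offset as the whole cause was argued against, since 57 genes of that depth were at least 2-fold below their common median and 0 above it, a count that no offset changes. A weaker pull-down stays open for them, because the densest 10% stood at -0.79 relative to the rest, and so does a loss of trimethylation at the most methylated genes in D546R.

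Chl1 was lower in D544R in H3K79me2. Chance clumps were argued against by the upper bound of its fragment interval, -1.22. A lower DNA copy number was argued against, if both marks were read in the same cells, by a ratio of -0.41 (-0.58 to -0.24) in H3K79me3. The gap between the marks depends on the scaling. With the silent genes as the reference all genes in D544R moved by -0.56 in H3K79me3 and by -0.039 in H3K79me2, which narrows it. No biological explanation other than the genotype or the culture could be named, and both remain untested.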

How the results depend on the processing

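Alternatives chosen after the values were seen were the fragment intervals, a mean of at least 1000, leaving out overlapping regions, and ranking or matching on counts per kb; the others were planned. Depth and design limit what can be said: 1 library per group gives no error between cultures, and ratios at a mean of 100 to 300 may carry clumps of duplicate reads. No paired analysis was possible because each group had 1 library. Keeping the row with the most counts per symbol was not run, since all 24012 symbols occur once. Of the values that answer a comparison, 262 stayed the same, 85 moved, 3 passed the limit anew, 3 no longer passed it and 1 reversed. A change of sign of a list median that lay inside the middle 95% is counted as moved, not as reversed. Of the other values 1313 stayed, 47 moved, 8 passed anew and 8 no longer passed. TMM factors and size factors over all 6 libraries moved none of the main counts by over 1.5-fold. Lower H3K79me2 at HoxA and the other targets in D546R kept its direction and its percentile outside the middle 95% under every alternative tried.

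Counts of genes past the rule are given as lower and higher, in the order D544R against WT, D546R against WT and D546R against D544R. In H3K79me2 they were 1 and 3, 77 and 79, and 78 and 69. With the silent genes as the reference they were 2 lower for the first, 144 and 30 for the next, and 132 and 29 for the last. Without a filter they were 366 and 643, 1963 and 1167, and 1939 and 945. At 1.5-fold they were 46 and 76, 379 and 792, and 398 and 714. With a mean of at least 300 they were 1 and 0, 33 and 8, and 34 and 11, and at 1000 they were 1 and 0, 20 and 1, and 21 and 2. Without overlapping regions 1 was higher in the first and 44 in the last, and with total counts 38 were higher in the last.

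In H3K79me3 they were 327 and 472, 965 and 751, and 899 and 625. With the silent genes as the reference they were 1998 and 97, then 2906 and 180. Without a filter they were 3005 and 3345, 4547 and 4261, and 4709 and 3909. At 1.5-fold they were 1242 and 1352, 2139 and 1817, and 2052 and 1660. With a mean of at least 300 they were 14 and 37, 249 and 84, and 169 and 68, and at 1000 they were 0 and 2, 72 and 0, and 39 and 0. Without overlapping regions they were 203 and 312, 575 and 461, and 554 and 378. With fragment intervals they were 178 and 313, 597 and 459, and 554 and 403. Fewer or more genes were tested in the filters and in the set without overlaps, and a lower threshold or wider interval changes a count by construction.

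With the silent genes as the reference, H3K79me3 medians in D544R became -0.35 for HoxA, -0.71 for the other fusion targets and -0.23 for mature myeloid genes, and -1.24 for the other targets in D546R. The difference between marks in D544R became -0.58 for the other targets and -0.50 for mature myeloid genes. That reference moved all genes by -0.56 in D544R in H3K79me3 and by -0.039 in H3K79me2. Of the mature myeloid genes 19 of 20 were then kept by the count minimum, and over all 20 the difference was -0.37.

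The percentile of mature myeloid genes in D544R in H3K79me2 was 95.4. It became 99.6 with members of a mean of at least 100, where 5 were left, 98.7 without matching and 99.1 on counts per kb. HoxA in D546R in H3K79me3 went from 0.14 to 3.27 with members of a mean of at least 100, where 3 were left. The other targets there went from 0 to 3.47 on counts per kb. The difference between marks of mature myeloid genes in D546R went from 2.45 to 6.88 with length matched; the cause was not tested.

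The concentration difference from WT in percentage points was -0.87 and -1.08 in H3K79me2 for D544R and D546R, and -1.21 and -2.95 in H3K79me3. With the top 5% of genes it was -0.73 and -1.79 in H3K79me2. With the top 25% it was -0.73 and -0.075 in H3K79me2, and -0.89 and -2.21 in H3K79me3. Ranked by counts per kb it was 0.23 and -0.18 in H3K79me2, a reversed sign for D544R, and -3.33 and -5.18 in H3K79me3; the cause was not tested.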

Other observations

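All tests in this part were chosen after the values they rest on were seen, and the genes below were picked from those past the 2-fold rule in D546R against WT. No group made from these genes was tested. Beyond the fusion targets, genes lower in both marks included, with H3K79me2 first, the remodeler genes Chd9 (-2.02 and -1.72), Arid1b (-1.19 and -1.35) and Arid2 (-1.10 and -1.78), the cohesin loader gene Nipbl (-1.13 and -2.10), the transcription kinase gene Cdk13 (-1.32 and -2.17) and the SUMO protease gene Senp6 (-1.11 and -1.83). The zinc finger genes Zfp800 (-1.83 and -2.60) and Zbtb25 (-1.80 and -2.26) were also lower in both, as were the neddylation gene Dcun1d1 (-1.49 and -2.77), the nuclear import gene Tnpo1 (-1.48 and -1.57) and the cell cortex gene Rdx (-1.10 and -2.32).

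Beside Chil3, Ccr1 and Ankrd22, the 13 genes higher in both marks in D546R included the selectin ligand gene Selplg (1.17 and 1.23), the integrin activator gene Fermt3 (1.09 and 1.30), the prostaglandin receptor gene Ptger2 (1.23 and 1.38) and the mitosis regulator gene Foxm1 (1.12 and 2.11). Single genes higher in H3K79me2 were the sialic acid receptor gene Cd33 (1.33), Pglyrp1 (1.33), Cd300lf (1.30), the oxidase gene Cybb (1.22), Lilrb4 (1.21) and the complement receptor gene C5ar1 (1.12). E2f2 (1.11), Cdc6 (1.10) and Cdca5 (1.07), which act in cell division, were also past the rule, while 0 members of the fixed cell cycle list were, and in H3K79me3 Mcm6 (-1.80) was lower. Tyms (-1.35) and Mcm3 (-1.01) were past the rule there too, but with fragment intervals that included no change. Genes past the rule in opposite directions, with H3K79me2 first, were Zfp84 (1.36 and -2.12), Il18r1 (1.21 and -1.14), Lgals9 (1.10 and -1.90), Dhx36 (1.02 and -1.04), Dis3 (1.01 and -1.04), Dagla (-1.14 and 1.21) and Pdk1 (-1.13 and 1.30).

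A hypothesis was a graded loss, with D544R between WT and D546R at the genes D546R lowers. The 77 genes lower in H3K79me2 in D546R, Meis1 and Hoxa9 among them, had a median of -0.14 in H3K79me3 in D544R (percentile 8.38), which was 9.68% of the difference in D546R with an upper bound of 23.6%. The 72 genes lower in H3K79me3 at a mean of at least 1000, Tsc22d2 and Runx2 among them, had a median of -0.031 in H3K79me2 in D544R (percentile 28.6), 1.74% with a bound of 6.39%. In H3K79me3 itself these 72 genes had a median of -0.36 in D544R (percentile 0, matched range -0.22 to -0.06). Of them 70 were below 0, but they were picked through the same WT library. The tests across marks measure the difference from matched genes, so a loss that matched genes share cancels. With the silent genes as the reference the median of all genes in H3K79me3 moved by -0.56 in each mutant, which these tests do not see. A loss of trimethylation alone would not appear in the H3K79me2 test. Beyond matched genes, and in the mark read, the tests argue against a loss in D544R of 50% or more of that in D546R. A smaller loss could not be excluded.

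Another hypothesis was that loss of H3K79me2 spreads to neighbours. Beside Tsc22d2, the genes Siah2 (-0.50), Serp1 (-0.51), Eif2a (-0.60) and Selt (-0.85) were below 0 in D546R in H3K79me2 without passing the rule. In H3K79me3 the same 4 genes passed it, at -2.15, -1.33, -1.45 and -1.79. The 205 genes within 100 kb of the genes that lose H3K79me2, without overlap, had a median of -0.22, and 137 were below 0. This lay below the matched range of -0.03 to 0.14, which may reflect spreading or domains that hold several targets. In H3K79me3 the 210 neighbours had a median of -0.14 inside the matched range of -0.17 to 0.11 (percentile 5.79), so over all neighbours spreading cannot be told apart from a general trend there, in spite of the low values beside Tsc22d2.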
